A study of Mus musculus with 12 samples.

How the data were processed

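RNA from mouse embryonic stem (ES) cells was hybridised to 12 two-channel oligonucleotide arrays with 60-base probes, per the labels. The labels name 3 cell lines: 1 wild-type (WT) parental line and 2 BAF250b-/- knockout (KO) clones, numbered 4 and 7. BAF250b is a subunit of the SWI/SNF complex, which remodels chromatin with energy from ATP. Each line was harvested at 18 h and 72 h after passaging, with 2 arrays for each of the 6 groups. Per the labels' protocols, sample RNA carried Cy3 and a pool of RNA from 11 mouse cell lines carried Cy5 on each array. No dyes were swapped, so a dye effect on a probe is the same on each array. Such an effect cancels in differences between groups but shifts the level of a probe against the reference. Nothing in the labels says that the 2 arrays of a group came from separate cultures in every case: both WT arrays at 18 h carry the culture letter A. The p-values therefore measure the spread between these arrays, which may be partly technical.

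The deposited scanner files hold spot intensities from Agilent Feature Extraction, the program named in the submitters' processing notes and per the file headers. The mean signal and background intensity of both channels were used as deposited. The deposited log10 ratio of red over green and the processed signal intensities served as alternatives. A table of 25674 probes, deposited with the series on a log10 scale, was set against the scanner values. Its columns followed log10 of green minus log10 of red plus the mean log10 of red, with r across probes between 0.9985 and 0.999, against 0.984 to 0.997 for the green channel alone. Its values therefore rise with the sample, and its column medians lay between 2.99 and 3.00. How that table's probes were chosen is not given in the sources used here.

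Both channels were corrected for background with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 under R 4.3.3. Control spots and spots carrying an outlier flag had no weight in loess, and flagged spots were left out. The sign was turned so that a log2 ratio above 0 means more RNA in the sample than in the reference. Of 44290 spots per array, 42034 were not controls, and averaging spots of 1 probe left 42006 probes. The planned unit was the gene, but the files pair no probe with a gene symbol, so the probe was the unit tested in each result. For the same reason the transcript of the targeted gene, the gene lists, the cell type markers and the rule for named genes, all fixed before the data were examined, were not analysed here. In place of that rule, the text names the 2 probes with the highest and the 2 with the lowest mean of the KO minus WT differences at 18 h and 72 h. These probes were past the threshold at both times, with all KO arrays beyond both WT arrays at each time and well above background on the higher side. This rule was set after the data were seen.

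One mean per group was fitted over all 12 arrays with limma (lmFit and eBayes), which gave 6 residual degrees of freedom plus 2.98 from the prior. Contrasts used Benjamini-Hochberg adjustment with a threshold of 0.05 and no limit on the fold. The planned filter, well above background in the sample channel on both arrays of at least 1 group, removed 0 probes, and between 99.9% and 100% of probes met it per array. A stricter filter added afterwards asked for a signal above the 95th percentile of the negative control spots, and 40734 probes passed it. On simulated arrays for KO versus WT at 18 h, with 40905 probes, the fit recovered 27 of 50 probes changed 1.25-fold, 47 of 50 changed 1.5-fold, 47 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 8 calls among unchanged probes.

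Probe groups were built without gene names, after the data were seen. Probes at least 2-fold above, or at least 2-fold below, the reference pool were taken from arrays outside the contrast under test. Groups sharing a sequence motif came from 21 motifs, of which 5 had at least 5 probes. Shifts were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. Alternatives covered background correction, normalisation, the channels used, filters, flags, eBayes options, thresholds, blocks and leaving out each array in turn. The lone array left in a group is then assumed to vary like the other groups.

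Feature extraction was run on 2 days per the file headers: WT and clone 4 on the first, clone 7 on the other. Day and clone 7 therefore cannot be told apart, and clone 4 against WT is the comparison within a day. Day cannot be fitted beside 6 group means, so it was added to a fit with 4 means of genotype by time. The alternatives naming a mean over the probes of a gene were not run.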

Results

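Gene expression was measured on 12 arrays of mouse ES cells: a WT line and BAF250b-/- clones 4 and 7, each at 18 h and 72 h after passaging, with 2 arrays per group. The question set by the design was how loss of this SWI/SNF subunit changes expression against the parental line at each time. Median sample intensity per array lay between 513.1 and 653, against 402.6 to 416.4 for negative control spots, and 89.9% to 97.3% of probes exceeded the 95th percentile of the negative controls. The number of arrays, 2 per group, limits the precision. Values on the arrays of a group correlated at r of 0.99 across probes, apart from clone 7 at 72 h with 0.952. The transcript of the targeted gene was not analysed here, so the genotype labels were not checked against it. Probes carry array identifiers, and no gene name is given for any of them.

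The first principal component held 66.3% of the variance. KO arrays at 72 h lay between 40.2 and 55.0 on it, and the other 8 arrays between -29.9 and -16.4.

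**Figure D1:**
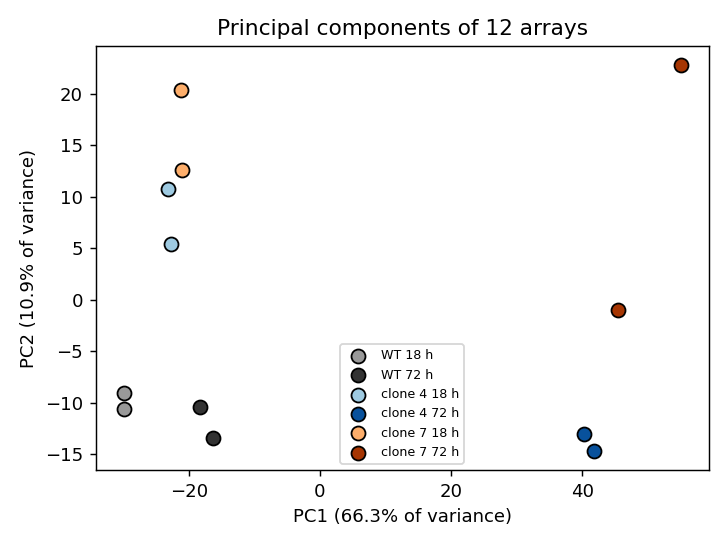
Principal components of the 12 arrays from log2(sample / reference), each point 1 array coloured by group, with PC1 (66.3% of variance) on the x axis and PC2 (10.9%) on the y axis. The 4 KO arrays at 72 h lie at 40.2 or more on PC1 and all others below 0.

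At 18 h, 5981 of 42002 probes differed between KO and WT, 2929 higher and 3052 lower in KO. Probe Z00035372-1 was higher in KO by 2.19 on the log2 scale (SE 0.08, adjusted p from limma 8.98e-07). Its mean was 0.69 ± 0.02 (SD, n = 2) in WT, 2.84 ± 0.08 in clone 4 and 2.92 ± 0.17 in clone 7. Probe Z00068163-1 was higher by 2.04 (SE 0.09), and by 1.23 without background correction. Probe Z00033250-1 was lower, with a difference of -2.27 (SE 0.06), and probe Z00033089-1 with -2.21 (SE 0.08). Most called differences were small: the median absolute difference was 0.26, and 89 probes differed at least 2-fold, 62 higher and 27 lower. Among called probes, 5818 had all 4 KO arrays beyond both WT arrays. Over all probes that share was 36.6%, where chance gives 13.3%. The share of called probes that were higher was 49.0%, against 30.6% with median centring and 60.0% from the sample channel alone. Without the first WT array at 18 h the count was 2753, and without the second 2845. With cell line as a random block (correlation within a line 0.10) it was 3438. The design holds 1 WT line, so the part of that correlation due to lines rests on the difference between the clones. Spread between WT lines is in none of these counts.

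At 72 h, 13494 of 42004 probes differed, 5907 higher and 7587 lower in KO. The named probes were chosen for the same direction at both times. Probe Z00035372-1 was higher by 3.13 (SE 0.08, adjusted p from limma 1.21e-08), reaching 3.72 ± 0.005 (SD, n = 2) in clone 4 and 3.78 ± 0.04 in clone 7. Probe Z00068163-1 was higher by 2.36 in clone 4 and 2.64 in clone 7, and by 1.53 over both clones without background correction. Probe Z00033250-1 differed by -2.49 (SE 0.06) and probe Z00033089-1 by -2.39 (SE 0.08). At least 2-fold differences numbered 855, with 363 higher and 492 lower. Of the probes called at 72 h, 3209 were called at 18 h in the same direction, 1076 in the opposite direction, and 9209 were not called at 18 h. Higher at both times were 1406 and lower at both 1803, where independent lists would share 412 and 551. Independent lists would hold 958 probes in opposite directions, so the 1076 were no fewer than that. The differences at 18 h and 72 h correlated at r of 0.337 across probes (Spearman's rho 0.218). From the sample channel alone 8817 probes were called and 57.7% of them were higher, against 43.8% with both channels.

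**Figure D2:**
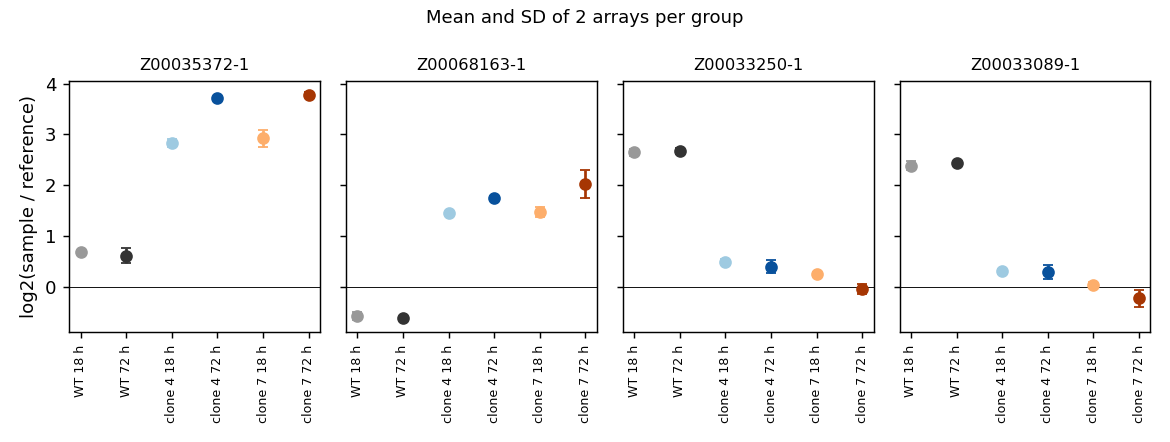
Log2(sample / reference) of the 4 named probes, 1 panel per probe; points are group means and bars the SD of 2 arrays. The left pair of probes is higher and the right pair lower in both clones than in WT at both times.

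Probes that stood at least 2-fold above the reference pool in WT at 18 h were followed as a group at 72 h. Of these 3611 probes, 2070 fell and 628 rose in KO against WT, with a median difference of -0.29 (-0.18 from the sample channel alone, with 1419 lower and 689 higher; camera p = 1.65e-13 with the preset correlation, p = 0.0318 with an estimated correlation). Among 36445 probes within 2-fold of the reference, 14.2% were lower and 12.8% higher. At 72 h the median of the group was 1.48 and 1.52 on the WT arrays, 1.28 and 1.23 on those of clone 4, and 1.30 on both of clone 7. Of 1950 probes at least 2-fold below the reference, 620 rose and 343 fell (camera p = 0.000796; p = 0.548 with an estimated correlation), with a median difference of 0.01. At 18 h, 3634 probes high in WT at 72 h went both ways, with 741 higher and 671 lower in KO. The camera test in limma gave p = 0.189 for this group with the preset correlation and p = 0.649 with an estimated one. No camera p-value in this paragraph was adjusted for the number of groups and contrasts tested. After Benjamini-Hochberg adjustment over these groups and contrasts, the camera p = 0.0318 with an estimated correlation would not stay below 0.05. Of 2001 probes at least 2-fold below the reference in WT at 72 h, 333 were lower and 239 higher in KO at 18 h, where camera in limma gave p = 0.00588 (downward) and p = 0.622 with an estimated correlation.

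**Figure D3:**
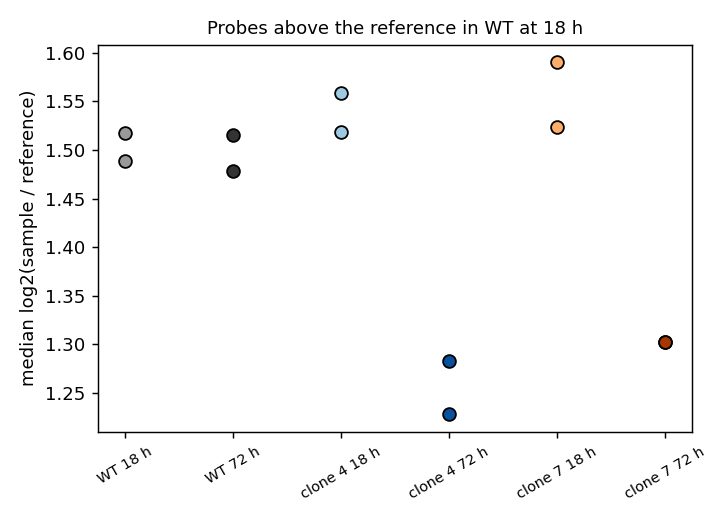
Median log2(sample / reference) of the 3611 probes at least 2-fold above the reference in WT at 18 h, 1 point per array; the y axis does not start at 0. KO arrays at 72 h lie lower than the other arrays. The set was chosen on the WT arrays at 18 h, so their own values are not independent of the choice.

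Over both times, 12602 probes differed between KO and WT, 5454 higher and 7148 lower. Their share of higher calls was 43.3%, against 55.5% from the sample channel alone. With extraction day as a block beside 4 means of genotype by time, the counts were 4002 at 18 h, 11782 at 72 h and 9558 over both times. WT and clone 4 share a day, and the other clone alone fills the other day. The day term therefore also takes up the mean of that other clone. Over both times the KO minus WT difference in this fit is that of clone 4. At each time the other clone adds only its change with time. These counts therefore cannot tell whether a difference shared by both clones is free of a day effect.

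Each clone was also set against the WT arrays. Clone 4, extracted on the same day as WT, differed at 3550 probes at 18 h and 11223 at 72 h. Clone 7 differed at 5848 and 14021. At 18 h the count of clone 4 was 1419 and 1642 without the first or second WT array and 2029 and 1346 without its own first or second array. Higher probes made up 49.0% of the calls of clone 4 at 18 h, against 38.2% with median centring and 70.1% from the sample channel alone. For clone 7 the share at 18 h was 48.3%, against 26.0%, 60.2% and, without background correction, 37.4%; at 72 h it was 43.0%, against 58.0% from the sample channel alone. Leaving out arrays, the count of clone 7 at 18 h was 3193 and 3017 without either WT array and 2934 without its own second array. At 18 h, 1415 probes were higher and 1562 lower in both clones, where independent lists of these sizes would share 117 and 130. At 72 h, 4158 were higher and 5609 lower in both, against 681 and 1232.5 (independent lists). Differences of the clones from WT correlated across probes at r of 0.848 at 18 h and 0.878 at 72 h, and simulated unchanged clones against shared WT arrays gave 0.50. The covariance was 0.0245 at 18 h and 0.0996 at 72 h, against 0.00507 simulated at each. With 1 WT array set against clone 4 and the other against clone 7, a check added after the data were seen, r was 0.681 and 0.753 at 18 h and 0.84 and 0.824 at 72 h for the 2 ways of doing so, with covariances of 0.0215 and 0.0229, and 0.0972 and 0.0965. Part of the excess in overlap of calls may come from the shared WT arrays. Setting 1 WT array against each clone does not remove all that is shared. Both WT arrays at 18 h carry the culture letter A. A deviation of that culture, or of the 1 WT line at either time, stays in both differences. The simulation leaves such a deviation out too. Probes are not independent replicates.

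Between the clones, 2346 probes differed over both times, 1211 higher and 1135 lower in clone 7. The count was 57 at 18 h and 2043 at 72 h, the latter falling to 927 without the second clone 7 array at 72 h. Over both times the count was 760 and 1075 without the first or second clone 4 array at 18 h, 1315 and 1171 without those at 72 h, 803 without the second clone 7 array at 18 h and 3990 without the first at 72 h. The share of higher calls was 51.6%, against 24.4% with median centring, 34.6% without background correction and 67.7% from the sample channel alone.

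Between 18 h and 72 h, 3488 probes changed in WT, 1675 higher and 1813 lower at 72 h, of which 37 by at least 2-fold. Each clone alone, on as many arrays as WT, changed at 12173 probes (clone 4) and 14046 (clone 7). With both clones averaged, on more arrays and so with more precision than in WT, 15957 changed in KO. Of these, 6963 were higher and 8994 lower, and 1031 changed by at least 2-fold. Higher probes made up 43.6% of these calls, against 51.4% from the sample channel alone, where the majority turned. The difference between these changes was tested by the interaction, which called 10036 probes, 4285 with a more positive and 5751 with a more negative change in KO. For clone 4 against WT, within 1 extraction day, the interaction called 8398 probes. From the sample channel alone it called 5154. The changes in WT and KO, measured on separate arrays, correlated at r of 0.41 across probes (Spearman's rho 0.28). They shared 1095 higher and 1428 lower probes, where independent lists would share 277.7 and 388. The changes in clones 4 and 7 correlated at r of 0.892. In WT, the sample channel alone called 809 probes, 68.9% of them higher against 48.0% with both channels. Leaving out either WT array at either time lowered the WT count to between 1570 and 1703.

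**Figure D4:**
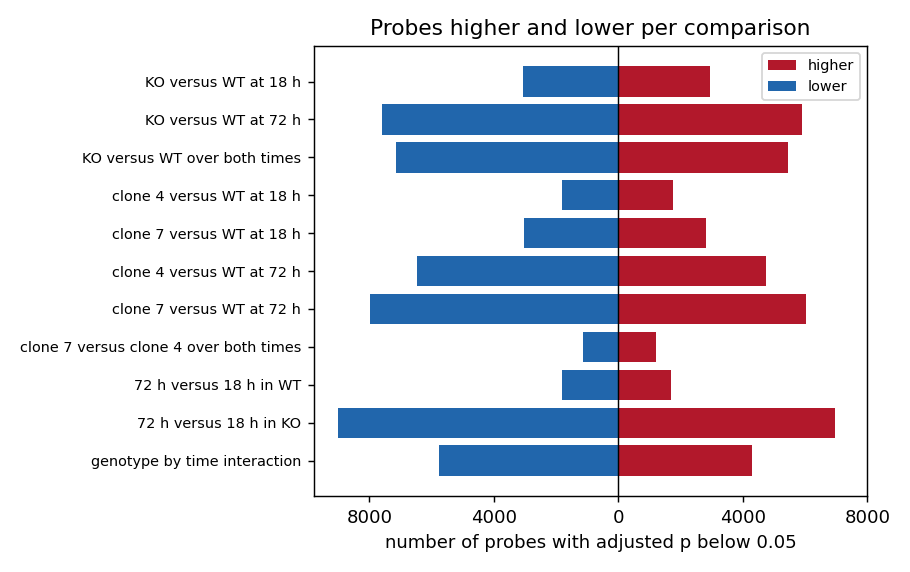
Number of probes with adjusted p below 0.05 (limma) in each comparison, higher to the right and lower to the left of 0. The bar for time in KO holds 6963 higher and 8994 lower probes, that for time in WT 1675 and 1813.

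The second clone 7 array at 72 h stood apart from its partner. The SD of the difference between these arrays was 0.254 over probes, against 0.0932 to 0.118 in the other groups. Of 490 probes over 2-fold lower on it, 447 lay in tiles of the array where the reference signal departed from the other arrays, which held 6.93% of all probes. Without that array the interaction called 10367 probes. Clone 7 against clone 4 then gave 93 probes at 18 h and 927 at 72 h, against 57 and 2043 with all arrays.

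**Figure D5:**
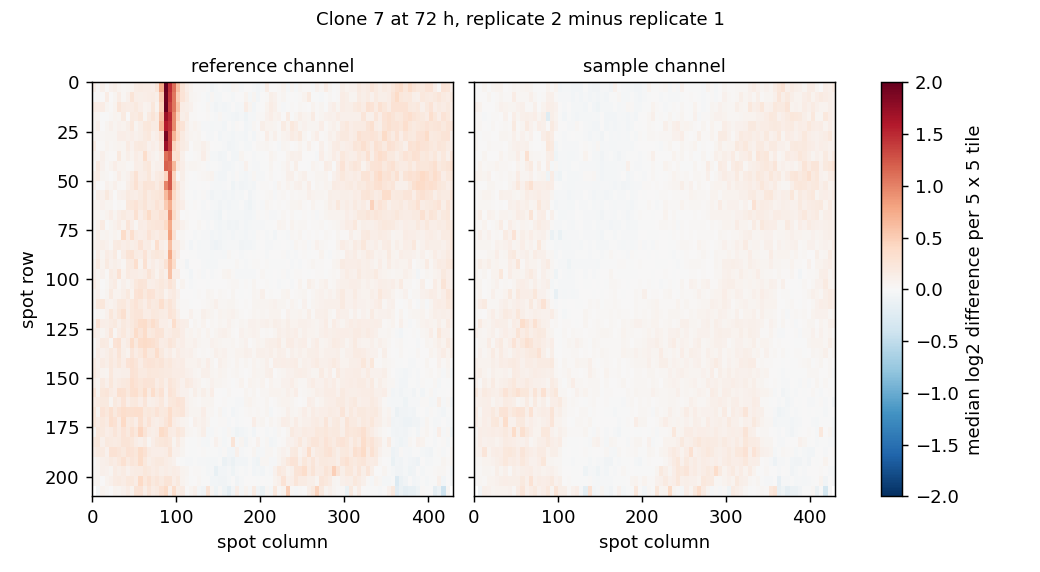
Median log2 difference in raw intensity between replicate 2 and replicate 1 of clone 7 at 72 h, by position on the array in tiles of 5 rows and 5 columns of spots; left the reference channel, right the sample channel. A vertical streak in the reference channel has no counterpart of its size in the sample channel.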

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

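The tests of extraction day, of the streaked array, of the size of the time change in the sample channel, of the difference between cell lines and of the apart-standing array were chosen after the results were seen. The count from the sample channel and the splits of the samples were set before.

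The genotype effect differed between the times at 10036 probes by the interaction. Each line was extracted on 1 day, so a day effect equal at both times would cancel in the interaction. Extraction day alone is also argued against by clone 4, extracted on the same day as WT, which gave 8398 probes. The streak on 1 array is argued against by 10367 probes without it. The prediction made for the reference channel came out in its favour: from the sample channel alone the count was 5154, below the bound of 10036 divided by 1.5. A count also falls with precision, and the median residual SD was 0.123 in the sample channel against 0.06 with both; the change with time in that channel, after removing noise, was still at least 2.44 times as large in the clones as in WT (3.18 times with both), which argues against the reference channel as the source of the larger change, but leaves the number of probes dependent on it. The 2 KO clones, lines of 1 genotype, differed from each other in the change with time at 3 of 42002 probes. The design holds 1 WT line, so whether other WT lines would differ from it as the clones do cannot be told. A biological effect of the genotype stays open as a hypothesis.

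The effects of the clones differed at 2346 probes over both times, and the change with time differed between the clones at 3 of 42002 probes (limma; 3812 at an unadjusted p under 0.05). In a fit with 2 groups of 4 arrays and no term for time, clone 7 against clone 4 called 2 probes and the highest other split, the one by time, 13171. With that split always among the 35, the share can be no lower than 2 of 35, too few splits for a share under 0.05. For time in KO, the real split called 13171 probes and the highest other split 2. As 1 of 35 splits gave as many, the lowest share possible, chance among single arrays is argued against. The arrays of a group may be partly technical repeats, and few splits keep the groups whole, so chance between cultures was not tested. For KO versus WT over both times, the real split called 1579 probes and the highest other split drawn 90. As 1 of 100 splits gave as many, chance among single arrays is argued against. Chance differences between cell lines are not, since only 3 splits keep the lines whole; the highest other split is one of them and separates clone 7, and with it the extraction day, from the rest. These fits used the 40905 probes with a value on all arrays.

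The second clone 7 array at 72 h lay apart from its partner. A streak in the reference channel is consistent with the strongest differences: 91.2% of the probes over 2-fold lower lay in masked tiles, which held 6.93% of all probes. The masked tiles lay between spot columns 1 and 430, so they were not the streak alone. The same rule masked 931 probes on the partner array. How many of the lower probes lay in the streak itself was not counted. The masked tiles do not account for the rest. Outside a wider mask the SD of the difference was still 0.137, above the 0.116 of the most variable other group. A position further along the time change is argued against by r = 0.0233 with the time change of clone 4 outside the mask. On the first principal component, computed with the masked probes included, the array did lie further out, at 55.0 against 45.5 for its partner. 4 tile settings were tried, and outside them the SD lay between 0.137 and 0.164.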

How the results depend on the processing

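The filter above negative controls, the removal of streaked tiles and the day block were chosen after seeing the data. Of the counts, 306 stayed within 1.5 times and 45 moved further. The 306 include settings that could not change a count. These were no filter on dim probes, where the planned filter removed 0, and Aquantile normalisation after loess, which alters no log ratio. All 260 alternative values of the named probes kept direction and threshold, though Z00068163-1 fell from 2.04 to 1.23 at 18 h without background correction. The named probes were chosen for large differences without overlap, so their stability was nearly fixed in advance. Median sample intensity was 513.1 to 653 against a background of 380 to 386; with the filter above negative controls the counts were 6105 at 18 h and 13574 at 72 h for KO versus WT. A fold of at least 1.5 lowered the counts by construction: 436, 3407 and 1027 for KO versus WT at 18 h, 72 h and both, 330 and 639 for clones 4 and 7 at 18 h, 3207 and 3844 at 72 h, 59 between clones, 257 and 3809 for time in WT and KO, and 3100 for the interaction. An adjusted p below 0.01 gave 2987 for KO versus WT at 18 h, 1504 and 2829 for clones 4 and 7 at 18 h, 442 between clones and 1604 for time in WT. Median centring gave 2307 for clone 4 at 18 h and 2054 for time in WT. The sample channel alone gave 8817 for KO versus WT at 72 h, 945 and 6638 for clone 4 at 18 h and 72 h, 4440 between clones, 809 for time in WT and 5154 for the interaction. Fitting 2 clones alone gave 798 between clones, and cell line as a random block 3438 for KO versus WT at 18 h. Apart from the thresholds and the fits of fewer samples, the cause was not tested. Leaving out single arrays gave 2753 to 6712 for KO versus WT at 18 h, 1346 to 3981 and 2934 to 6585 for clones 4 and 7 at 18 h, 760 to 3990 between clones and 1570 to 3860 for time in WT. The replicate numbers did not pair most groups: 2 of 15 pairs of groups had deviations correlated over 0.1, and r ranged from -0.153 to 0.364. The highest r was that of clones 4 and 7 at 18 h. Their arrays with the same replicate number shared deviations, so the KO arrays at 18 h were not fully independent. The lowest r was that of clone 4 at 72 h with clone 7 at 18 h. With the replicate block the counts were 5873 at 18 h, 13324 at 72 h and 9954 for the interaction, and no count moved by over 1.5 times. The gene list alternatives and the mean over probes of a gene were not run, since no probe was tied to a gene.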

Other observations

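The tests of the probes above the reference were chosen after the results were seen; the matched lists of zinc finger probes were set before their result. Sequence motifs give probe groups without gene names. Of the probes, 24 encode the linker between neighbouring C2H2 zinc fingers, the repeat of Kruppel-type DNA-binding proteins. At 72 h, 23 of them fell and 1 rose in KO against WT, with a median difference of -0.68 (camera adjusted p over 20 tests 3.39e-09; adjusted p = 0.545 with an estimated correlation). With time in KO, 23 fell and 1 rose (median -0.56), and with time in WT 0 were called by limma (median -0.06). The interaction called 21, of which 20 were more negative. Both clones showed it, with 23 probes lower in clone 4 and 22 in clone 7. Related sequences can cross-hybridise, so these are not 24 independent measurements. Camera with the preset correlation, which compares a group with other probes, called no other group at 72 h: 143 probes with AU-rich elements had a median of -0.04 (adjusted p = 0.461) and 2836 with a poly(A) signal -0.01 (adjusted p = 0.978), while 6 homeodomain probes (adjusted p = 0.978) and 5 core histone probes (adjusted p = 0.461) had 0 and 1 called. Fry asks whether the members move one way on balance and compares them with no other probes. By fry in limma the adjusted p over 20 tests was 5.45e-05 both for the zinc finger probes and for AU-rich elements (33 fell, 16 rose). It was 0.0059 in limma for the poly(A) signal (668 fell, 544 rose), with an adjusted p of 0.0167 for core histones and 0.497 for the homeodomain. At 18 h, 9 zinc finger probes fell (camera adjusted p = 0.0026; adjusted p = 0.619 with an estimated correlation), and 2 core histone probes fell (camera adjusted p = 0.0156; adjusted p = 0.545 with an estimated correlation).

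The fall at 72 h of probes high in ES cells may reflect a loss of RNAs that the WT line holds above the reference, as a hypothesis. Compressed log ratios would bring low probes nearer to 0 as well. In clone 4 high probes lay 16.2% nearer to 0 than in WT and low probes 3.56%; in clone 7 the values were 13.0% and -3.78%. The median difference of the low probes was 0.08 and -0.05 where compression needs 0.26 and 0.21. Their spread across probes (median absolute deviation) was 0.301 and 0.429, so single low probes decide nothing. The median of the low probes varied less between arrays at 72 h. Its SD (n = 2) was 0.018 in WT, 0.0188 in clone 4 and 0.0198 in clone 7. These medians argue against compression of high and low ratios by an equal share as the whole cause. Changes of the low probes themselves were not separated from it. Scaling the arrays to 1 spread of log ratios left the fall in place: the median of the high probes was -0.38 with 2281 lower and 439 higher (-0.29 with 2070 and 628 without scaling), and that of the zinc finger probes -0.85. Most of the move in the high probes came from clone 7, at -0.451 with scaling and -0.280 without. Its arrays were wider than those of WT (median absolute deviation 0.302 and 0.332), so scaling could not lessen its fall. In clone 4 alone the median of the high probes was -0.312 with scaling and -0.297 without. The clone 4 arrays were no narrower than those of WT (median absolute deviation 0.281 and 0.276, against 0.273 and 0.283). With spreads this alike, scaling could hardly lessen the fall in clone 4 either. An array compressed by 1 factor would be narrower, unless real differences widened it again, which was not tested. Neither the scaling nor the spread therefore decides on compression by 1 factor per array. Compression of high ratios alone was not tested and stays open. The zinc finger probes fell further than most of 10000 random lists matched on WT level at 18 h. Their median stood at percentile 0.29 of the list medians, where the lists had a median of -0.27. Members of the lists were drawn independently, while zinc finger probes can cross-hybridise, so this percentile may be too extreme. Camera with an estimated correlation gave adjusted p = 0.545 for the zinc finger probes at 72 h. Under the sample channel alone the medians were -0.18 for the high probes and -0.80 for the zinc finger probes. Of the 24 zinc finger probes, 21 belong to the high probes. Apart from the motifs, what the RNAs encode was not analysed here.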
